A study of Mus musculus with 8 samples.

How the data were processed

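The study sorted CD4+ T cells from the livers of Aire-deficient C57BL/6 mice that carried a GFP reporter of Foxp3, at 5 and 10 days of age. Per the labels, cells were double-sorted into lysis buffer, polyadenylated RNA was primed with an anchored oligo(dT), and amplified cDNA was tagmented and sequenced as short paired reads on a NextSeq500. The authors deposited a single table of raw counts per gene symbol with 1 column for each of the 8 libraries. STAR 2.5.4, featureCounts and the mouse build mm10 are named in the submitters' processing notes. The annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here, so genes that overlap on opposite strands and close paralogs (H2-Q genes, ribosomal proteins) may share counts. Each library was sequenced as 1 sample and no library was pooled or left out of the main analysis.

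The table was read as it stood, and the values were checked to be whole numbers. Its 8 columns were matched to the samples by title, with 0 left unmatched. Library totals, in the order PD-1- then PD-1+, were 3019551 and 2215852 for 5-day replicate 2, 1706991 and 2365447 for 5-day replicate 3, 2832550 and 2843311 for 10-day replicate 1, and 1473216 and 2791009 for 10-day replicate 2. Between 16790 and 20424 gene symbols were detected per library. Gene models that overlap ribosomal RNA took 3.67 to 7.17% of the counts, mitochondrial genes 1.20 to 2.66% and ribosomal protein genes 2.24 to 4.84%. The chi-square per degree of freedom between the 2 replicates of a group was 6.50 (5-day PD-1-), 4.00 (5-day PD-1+), 6.30 (10-day PD-1-) and 8.61 (10-day PD-1+), and their Spearman correlation 0.958, 0.971, 0.962 and 0.967, so the spread exceeded counting error. Sex was read from Xist and from Y-linked genes.

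Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults given the 4 groups (11490 of 52997 symbols), libraries were scaled by TMM, and robust quasi-likelihood fits were tested with F tests. An additive model of age and PD-1 gave the PD-1 effect over both ages and the age effect over both populations. A model of the 4 groups gave PD-1+ against PD-1- cells at each age, 10 against 5 days in each population, and the interaction. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene is called at an adjusted p below 0.05. Standard errors of log2 fold changes are |log2 fold change| divided by the square root of F. CPM values are counts scaled to the summed counts of the tested genes times the TMM factor of the library. Their ± is the standard deviation between libraries. Where a population had 0 to 3 counts, the pooled CPM of both populations used library totals without TMM factors. Where 1 side had 0 counts in all its libraries together, the fold is given as at least the ratio to a floor of 3 counts over that side, and where it had 1 to 3 counts CPM alone is given. Principal components were computed from log2 CPM with a prior count of 2. Coordinates of genes are from GENCODE M21 on GRCm38.

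Gene lists were fixed before the data were examined: 30 lists, of which 10 hold markers of other cell types (hepatocyte, erythroid, macrophage and Kupffer, neutrophil, B, dendritic, NK and innate lymphoid, gamma-delta T, CD8 T, endothelial and stromal). The other 20 lists cover T cell receptor activation, co-inhibitory receptors, anergy, naive quiescence, mitosis, DNA replication, Th1 and cytotoxic genes, Th2, Th17, follicular helper, regulatory T cell genes, tissue homing and residency, interferon response, glycolysis, oxidative phosphorylation, fetal and neonatal genes, recent thymic emigrants, innate-like and NKT cells, other cytokines, and stress and dissociation. Of 438 symbols, 23 are in more than 1 list, and T cells themselves express many genes of the dendritic, NK and gamma-delta lists. The 26 lists with at least 3 tested members were tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Counts of called members are given after adjustment over all genes and over the list alone.

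Named genes were chosen for each comparison by a rule set in advance: the 12 largest upward and 8 largest downward log2 fold changes among called genes with a mean log2 CPM of at least 4 and no overlap between the libraries of the 2 sides, leaving out receptor variable segments and unnamed models. To these were added up to 4 members of each list with the smallest p, and a fixed set with Pdcd1, Foxp3, Cd4, Izumo1r, Nt5e, Ctla4, Ccr7, Ifng, Tbx21, Bcl6, Gata3, Il2, Lin28b and Alb. A gene chosen in 1 comparison may also be given in another, and the text does not print every gene the rule gives. Results of some genes are not reported here.

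The procedure was tested on simulated data with the totals and spread of these libraries, 100 genes changed 2-fold and 100 changed 4-fold. It recovered 56% and 85% for PD-1 over both ages and 52% and 88% for age over both populations. For PD-1 at 5 days it recovered 21% and 68%, for age in PD-1+ cells 24% and 79%, and for the interaction 7% and 40%. In the same order, 16 (of 10867 tested), 9, 7, 6 and 3 unchanged genes were called. Their share of all calls was each time above the nominal 0.05, in 1 simulated draw per comparison. In these simulations a 2-fold change in PD-1 at 5 days or with age in PD-1+ cells was missed more often than found. Far more genes were called in the data in these comparisons than were changed in the simulations. The p cut-off after adjustment therefore differed, and recovery in the data may differ too. The other comparisons within 1 age or population were not simulated. A simulated list changed 1.5-fold was called by camera, and 0 of 25 other lists were. Genes were simulated independently of each other, whereas list members in the data moved together (estimated correlation 0.877 for mitosis genes, PD-1 over both ages). The simulation therefore does not show how often camera at the preset correlation calls unchanged lists in such data.

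Alternatives tried were RLE and upper-quartile scaling, no filter and a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom with quality weights, glmTreat against a fold of 1.5, each library left out in turn, thinning to the smallest total (seed 11), removal of hepatocyte, erythroid and mitochondrial genes, and a replicate block. Added once the libraries had been seen were a term for sex, leaving out the male pair, and removal of gene models that overlap ribosomal RNA. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Transcript isoforms and alleles were not analysed here, and no Aire-sufficient or adult T cells were used here.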

Results

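RNA was sequenced from CD4+ T cells of the livers of 5-day-old and 10-day-old C57BL/6 mice lacking Aire, the thymic regulator that drives self-antigen expression in medullary epithelium. The sorted cells were live, CD45+ and TCRb+ and lacked the GFP reporter of Foxp3. They were divided by surface PD-1, the inhibitory receptor encoded by Pdcd1. There were 8 libraries in 4 groups, with 2 libraries each of PD-1- and PD-1+ cells at each age, and no Aire-sufficient mice. Library totals ranged from 1473216 counts in PD-1- 10-day replicate 2 to 3019551 in PD-1- 5-day replicate 2. Of 52997 gene symbols, 11490 had enough counts to be tested. The labels do not say which libraries came from separate animals, so every p-value here measures only the spread between these libraries, part of which may be technical. Values with ± are log2 fold changes with standard errors, or mean CPM (counts scaled by library size and TMM factor) with standard deviations.

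Aire had 2 counts in PD-1+ 5-day replicate 3, 1 count in PD-1- 10-day replicate 2 and 0 in the other 6 libraries. T cells normally transcribe little of it, so these counts leave the genotype untested. Pdcd1, the sorted marker, was at 1.09 ± 0.744 CPM in PD-1- and 293 ± 33.4 CPM in PD-1+ cells at 5 days, and at 1.62 ± 0.464 and 597 ± 139 CPM at 10 days (n = 2 per group). Foxp3, the lineage factor of regulatory T cells, had 17, 10, 32 and 15 counts in the PD-1- libraries and 1, 2, 1 and 0 in the PD-1+ libraries, each in the order 5-day replicates 2 and 3, then 10-day replicates 1 and 2. In the same order, Cd4 had 2193, 1226, 2888 and 1101 counts in PD-1- cells and 1330, 1579, 4279 and 3802 in PD-1+ cells, against 1 to 40 counts of Cd8a in any library. Both 5-day libraries numbered 3 came from males, with 672 and 601 counts from Y-linked genes and 5 and 1 counts of Xist. The other 6 libraries had 698 to 1842 counts of Xist, the transcript of the inactive X chromosome, and 0 from Y-linked genes. All 10-day libraries were therefore female, and sex and age were partly mixed. Actb, a cytoskeletal gene, took 1.24 to 1.57% of the counts of PD-1- libraries and 2.90 to 5.33% of those of PD-1+ libraries. The first principal component held 59.3% of the variance and separated PD-1+ from PD-1- libraries, and the second held 15.5%.

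**Figure D1:**
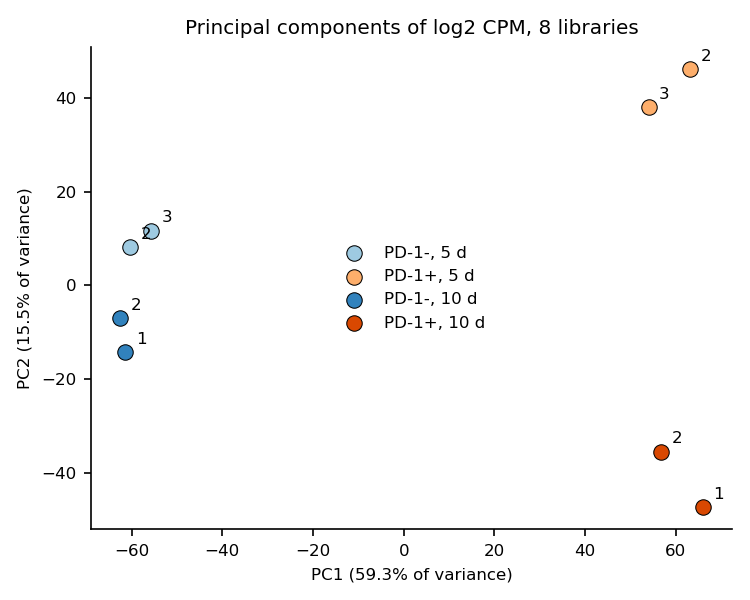
Principal components of the 8 libraries, computed from log2 CPM of the tested genes. Colour gives the sorted population and age, and the number beside each point is the replicate number.

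Over both ages together, Pdcd1, Ifng, Il10 and Lag3 were higher and Igfbp4 was lower in PD-1+ than in PD-1- cells of the neonatal liver (n = 4 libraries per population). Pdcd1 itself was higher by 8.25 ± 0.25 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.63e-11). Ifng, the macrophage-activating cytokine of Th1 cells, was at 2.78 ± 2.28 CPM in PD-1- and 489 ± 138 CPM in PD-1+ cells (7.43 ± 0.60, edgeR adjusted p = 8.85e-05). Il10, which encodes an inhibitory cytokine, differed by 7.80 ± 0.62 and Lag3, a co-inhibitory receptor for MHC class II, by 6.88 ± 0.55 (edgeR adjusted p = 3.72e-05 and 5.01e-05). Igfbp4, a secreted binding protein for insulin-like growth factors made by naive T cells, ran the other way, at 1763 ± 173 CPM in PD-1- and 56.7 ± 52.7 CPM in PD-1+ cells (-5.33 ± 0.60, edgeR adjusted p = 0.000866). With edgeR and Benjamini-Hochberg adjustment, 2512 genes were higher and 2249 lower in PD-1+ cells, 1362 and 1258 of them by 2-fold or more. Which direction held more genes depended on the scaling, with 2194 higher and 2602 lower under upper-quartile normalization (1796 and 2141 at 5 days, 1660 and 1759 at 10 days).

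Other genes with large differences upward included Lgals3, a galactoside-binding lectin (6.96 ± 0.28), Bhlhe40, a repressor needed for effector cytokine production (6.79 ± 0.65), Tigit, a co-inhibitory receptor for CD155 (6.36 ± 0.33), and the calcium-binding genes S100a6 (6.04 ± 0.30) and S100a4 (5.85 ± 0.36). Among the genes with large differences downward were Ly6c1, a surface antigen of resting T cells (-4.87 ± 0.40), Pdlim4, an adaptor of actin (-4.86 ± 0.33), Ifngr2, a chain of the interferon-gamma receptor (-4.80 ± 0.38), Atp1b1, a sodium pump subunit (-4.61 ± 0.22), and Gpr83, a neuropeptide receptor (-4.46 ± 0.29). Among these 10 genes the edgeR adjusted p was 1.40e-09 to 0.000373. Pdcd1 lies on chromosome 1 from 94038305 to 94052553, Ifng on chromosome 10 from 118441046 to 118445892, Lag3 on chromosome 6 from 124904361 to 124911705 and Igfbp4 on chromosome 11 from 99041244 to 99054392 (GRCm38). Several cytokines had 0 counts in all 4 PD-1- libraries together. Il21, which helps B cells, was at 62.4 CPM in pooled PD-1+ libraries, at least 188-fold higher. Il5, a growth factor of eosinophils chosen after its values were seen, was at least 62.8-fold higher, and Il4, the cytokine that drives Th2 differentiation and IgE switching, at least 28-fold, taking 3 counts over the PD-1- group as the floor. These floors cover counting error only. Il2, the T cell growth factor, and Areg, an epithelial repair factor, had 2 counts each in the PD-1- libraries, 0.221 CPM, against 16.8 and 42.9 CPM in PD-1+ libraries.

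**Figure D2:**
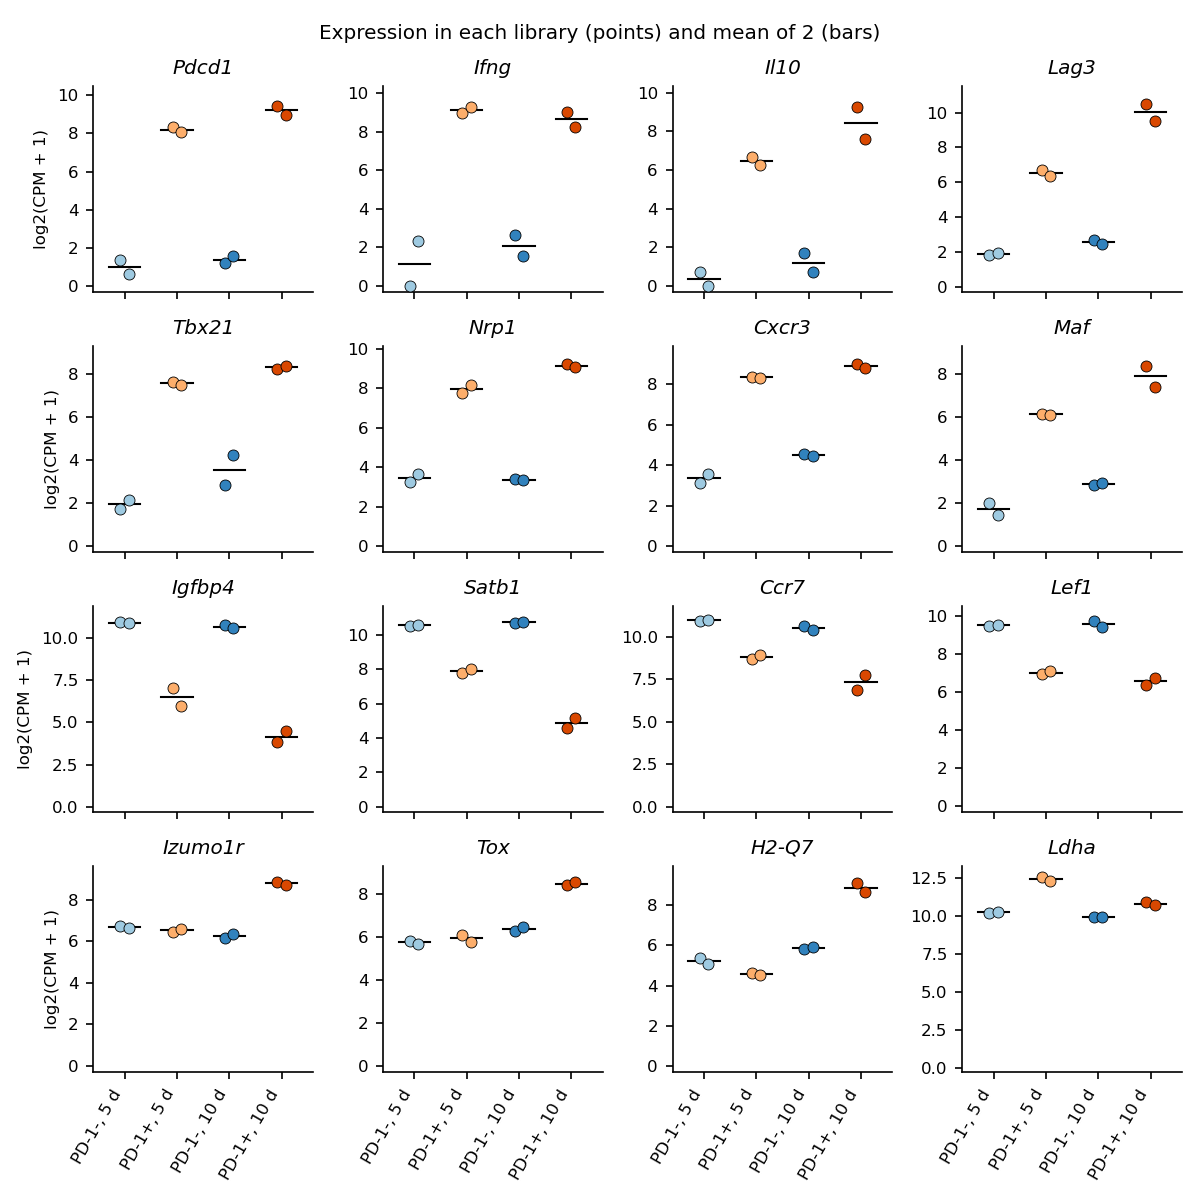
Expression of 16 genes in each library, with the mean of each group of 2 as a bar.

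Genes induced by T cell receptor signalling were mostly higher in PD-1+ cells, where 16 of 22 were higher, 0 lower and 6 not called. Receptor activation genes adjusted over the list alone gave 16 higher and 0 lower (camera adjusted p = 1.45e-17, adjusted p = 0.00531 with an estimated correlation). The memory marker Cd44 differed by 3.003 ± 0.14, the nuclear receptor Nr4a2 by 4.14 ± 0.21 and Tnfrsf18, the costimulatory receptor GITR, by 3.15 ± 0.20. Of co-inhibitory receptors and their regulators, which included the sorted Pdcd1, 10 of 12 were higher, 0 lower and 2 not called. Co-inhibitory genes adjusted over the list alone gave 11 higher and 0 lower (camera adjusted p = 3.87e-17, adjusted p = 0.0137 with an estimated correlation). Ctla4, a competitor of CD28 for B7 ligands, was higher by 4.45 ± 0.40 and Entpd1, the ectoenzyme CD39 that degrades extracellular ATP, by 4.08 ± 0.32. Anergy genes were divided: 7 of 15 were higher, 2 lower and 6 not called. Anergy genes adjusted over the list alone gave 7 higher and 3 lower (camera adjusted p = 0.0114, adjusted p = 0.268 with an estimated correlation). Nrp1, a semaphorin receptor (5.31 ± 0.25), and the E3 ligase Rnf128 (5.77 ± 0.44) were higher, while Dgka, a kinase that removes diacylglycerol, was lower (-1.80 ± 0.13). Izumo1r, the folate receptor 4 gene used with CD73 to mark anergic cells, was not called over both ages (1.22 ± 0.62, edgeR adjusted p = 0.175), whereas Nt5e, which encodes CD73, was higher (3.09 ± 0.33). Among regulatory T cell genes, 11 of 15 were higher, 2 lower and 2 not called. Regulatory T cell genes adjusted over the list alone gave 11 higher and 2 lower (camera adjusted p = 1.46e-09, adjusted p = 0.0126 with an estimated correlation). Ikzf2, the zinc-finger factor Helios, was higher (3.65 ± 0.25), but Foxp3 was lower (-4.04 ± 0.72, edgeR adjusted p = 0.000404) at a level of 7.83 ± 2.59 CPM even in PD-1- cells.

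Genes of several helper programmes were higher in the PD-1+ population. Of Th1 and cytotoxic genes, 15 of 18 were higher, 0 lower and 3 not called. Th1 and cytotoxic genes adjusted over the list alone gave 16 higher and 0 lower (camera adjusted p = 2.07e-16, adjusted p = 0.0353 with an estimated correlation). Tbx21, the Th1 master regulator, differed by 5.32 ± 0.31, the chemokine receptor Cxcr3 by 4.77 ± 0.18 and the death ligand Fasl by 4.21 ± 0.28. Of Th2 genes, 9 of 9 were higher, 0 lower and 0 not called. Th2 genes adjusted over the list alone gave 9 higher and 0 lower (camera adjusted p = 3.11e-10, adjusted p = 0.0145 with an estimated correlation). The skin and lung homing receptor Ccr8 was higher by 3.64 ± 0.34, its relative Ccr4 by 2.83 ± 0.37 and the Th2 factor Gata3 by 0.73 ± 0.15 (edgeR adjusted p = 0.00145). Th17 genes were mostly below detection: 1 of 3 were higher, 0 lower and 2 not called. Th17 genes adjusted over the list alone gave 1 higher and 0 lower (camera adjusted p = 0.517). Rora, a nuclear receptor shared by Th17 and innate-like cells, was the gene called (2.46 ± 0.27), and Il17a had 1 count in all 8 libraries. Of follicular helper genes, 8 of 13 were higher, 0 lower and 5 not called. Follicular helper genes adjusted over the list alone gave 9 higher and 0 lower (camera adjusted p = 7.78e-08, adjusted p = 0.138 with an estimated correlation). Maf, a factor behind IL-21 and IL-10 production, was higher by 5.12 ± 0.27 and the costimulator Icos by 1.75 ± 0.13, while Bcl6, the repressor that defines follicular helper cells, was not called (0.89 ± 0.38, edgeR adjusted p = 0.0745). Of tissue homing and residency genes, 17 of 23 were higher, 0 lower and 6 not called. Homing genes adjusted over the list alone gave 19 higher and 0 lower (camera adjusted p = 7.37e-24, adjusted p = 0.0126 with an estimated correlation). They were led by Cxcr3, Lgals3 and Rgs1, a brake on chemokine receptor signalling (3.26 ± 0.21).

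Naive T cell genes were almost uniformly lower in PD-1+ cells, where 0 of 19 were higher, 18 lower and 1 not called. Naive genes adjusted over the list alone gave 0 higher and 18 lower (camera adjusted p = 1.19e-26, adjusted p = 0.0126 with an estimated correlation). The lymph node homing receptor Ccr7 was lower (-2.66 ± 0.24, edgeR adjusted p = 1.05e-05), as were Lef1, a factor of the Wnt pathway that keeps T cells immature (-2.77 ± 0.16), and the quiescence factor Klf3 (-2.26 ± 0.13). Of genes kept by recent thymic emigrants, 0 of 6 were higher, 6 lower and 0 not called. Emigrant genes adjusted over the list alone gave 0 higher and 6 lower (camera adjusted p = 0.000252, adjusted p = 0.0353 with an estimated correlation). The gut homing receptor Ccr9 differed by -3.14 ± 0.32 and the lipid presenter Cd1d1 by -1.57 ± 0.22. Of interferon response genes, 1 of 27 were higher, 11 lower and 15 not called. Interferon response genes adjusted over the list alone gave 1 higher and 11 lower (camera adjusted p = 0.0331, adjusted p = 0.617 with an estimated correlation). The RNA sensor Ddx58 (-1.25 ± 0.19) and the RNA-binding Oasl2 (-3.80 ± 0.66) were lower, and the exonuclease Isg20 was the 1 member higher (1.29 ± 0.29).

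Proliferation and metabolism genes were higher in PD-1+ cells. Of DNA replication genes, 22 of 23 were higher, 0 lower and 1 not called. DNA replication genes adjusted over the list alone gave 23 higher and 0 lower (camera adjusted p = 2.32e-20, adjusted p = 0.0264 with an estimated correlation). The helicase subunits Mcm5 and Mcm6 were higher by 2.13 ± 0.14 and 2.10 ± 0.13. Of mitosis genes, 19 of 23 were higher, 0 lower and 4 not called. Mitosis genes adjusted over the list alone gave 22 higher and 0 lower (camera adjusted p = 3.95e-05, adjusted p = 0.478 with an estimated correlation). The chromosomal kinase Aurkb differed by 1.14 ± 0.17. Of glycolysis genes, 15 of 16 were higher, 0 lower and 1 not called. Glycolysis genes adjusted over the list alone gave 15 higher and 0 lower (camera adjusted p = 8.25e-10, adjusted p = 0.227 with an estimated correlation). Gapdh (1.99 ± 0.16), Pfkp (1.67 ± 0.17) and Hk1 (1.18 ± 0.13), which encode enzymes of sugar breakdown, had the smallest p-values. Of oxidative phosphorylation genes, 16 of 24 were higher, 0 lower and 8 not called. Respiratory genes adjusted over the list alone gave 17 higher and 0 lower (camera adjusted p = 0.000430, adjusted p = 0.360 with an estimated correlation). Higher ones included the respiratory subunits Cox5a (1.14 ± 0.14) and Sdhb (1.03 ± 0.12). Of stress and dissociation genes, 8 of 16 were higher, 2 lower and 6 not called. Stress genes adjusted over the list alone gave 8 higher and 3 lower (camera adjusted p = 0.0944). The AP-1 gene Junb differed by 1.35 ± 0.13 and the phosphatase Dusp1 by 1.23 ± 0.13, against -1.45 ± 0.24 for Jun.

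**Figure D3:**
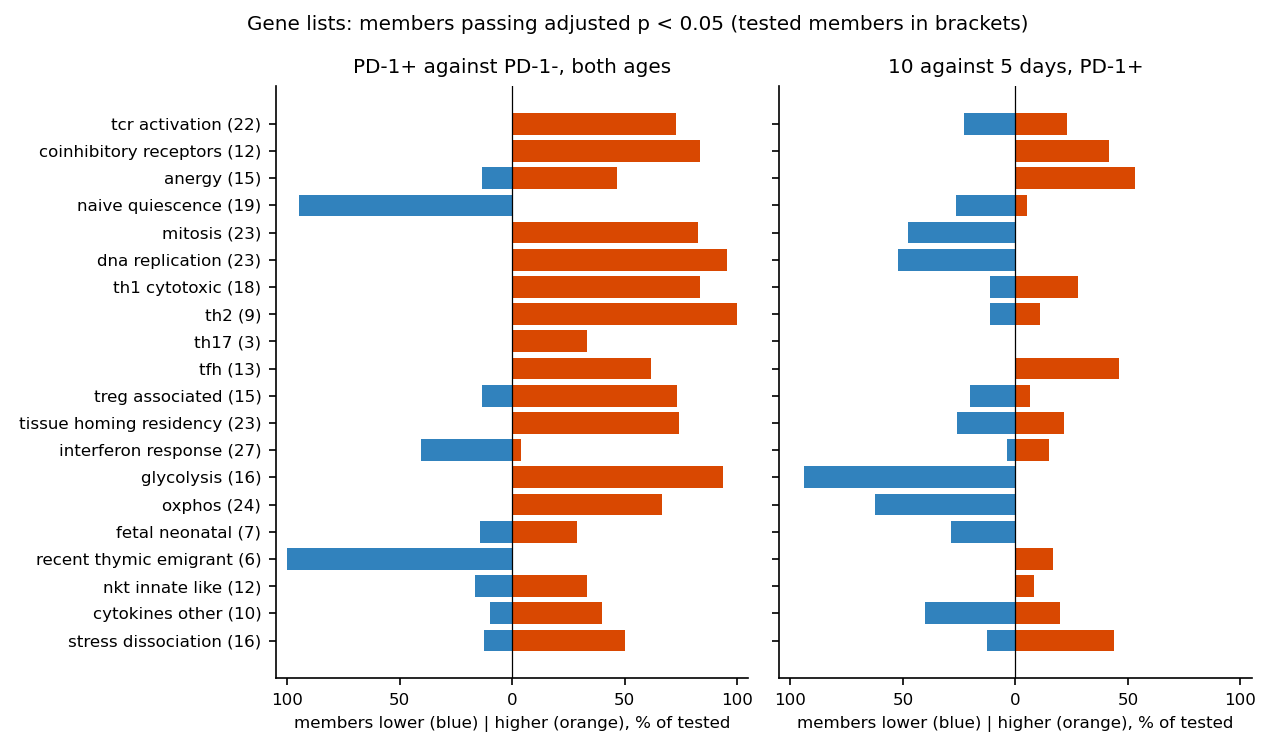
Percent of tested members of each fixed list called higher or lower in PD-1+ than in PD-1- cells, and at 10 than at 5 days in PD-1+ cells.

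Of other cytokines, 4 of 10 were higher, 1 lower and 5 not called. Cytokine genes adjusted over the list alone gave 4 higher and 1 lower (camera adjusted p = 0.0399, adjusted p = 0.156 with an estimated correlation). Of innate-like and NKT genes, 4 of 12 were higher, 2 lower and 6 not called. Innate-like genes adjusted over the list alone gave 5 higher and 2 lower (camera adjusted p = 0.0944). The shared IL-2 and IL-15 receptor chain Il2rb was higher by 4.11 ± 0.23 and the HVEM receptor Cd160 by 1.98 ± 0.29. Of fetal and neonatal genes, 2 of 7 were higher, 1 lower and 4 not called. Fetal genes adjusted over the list alone gave 2 higher and 1 lower (camera adjusted p = 0.449). Lin28b, an RNA-binding protein of fetal blood formation, was not called (0.23 ± 0.89, edgeR adjusted p = 0.865). Plagl1, an imprinted zinc-finger gene of fetal growth, had 0 counts in PD-1- libraries and 9.59 CPM in PD-1+ libraries, at least 28.9-fold higher. Across all 26 lists tested, 17 were called by camera, 14 upward and 3 downward, 9 with an estimated correlation and 19 by fry.

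Transcripts of other liver cells were low but uneven. Of hepatocyte genes, 4 of 5 were higher, 0 lower and 1 not called. Hepatocyte genes adjusted over the list alone gave 4 higher and 0 lower (camera adjusted p = 0.0420, adjusted p = 0.360 with an estimated correlation). Alb, the plasma albumin gene, was at 2.59 ± 3.67, 21.2 ± 13.7, 1.62 ± 0.454 and 39.6 ± 3.88 CPM in 5-day PD-1-, 5-day PD-1+, 10-day PD-1- and 10-day PD-1+ libraries (3.56 ± 0.61, edgeR adjusted p = 0.000991). Of macrophage and Kupffer cell genes, 1 of 6 were higher, 1 lower and 4 not called. Macrophage genes adjusted over the list alone gave 1 higher and 1 lower (camera adjusted p = 0.496). Of B cell genes, 0 of 7 were higher, 1 lower and 6 not called. B cell genes adjusted over the list alone gave 0 higher and 1 lower (camera adjusted p = 0.496). The IgM heavy chain Ighm was lower (-1.01 ± 0.13). Of dendritic cell genes, 1 of 7 were higher, 0 lower and 6 not called. Dendritic genes adjusted over the list alone gave 1 higher and 0 lower (camera adjusted p = 0.155). The chemokine receptor Xcr1 was higher (5.04 ± 0.41). Of NK and innate lymphoid genes, 0 of 7 were higher, 2 lower and 5 not called. NK genes adjusted over the list alone gave 0 higher and 1 lower (camera adjusted p = 0.242). Of gamma-delta T cell genes, 2 of 5 were higher, 0 lower and 3 not called. Gamma-delta genes adjusted over the list alone gave 2 higher and 0 lower (camera adjusted p = 0.449). The coreceptor Cd8b1 was lower (-1.92 ± 0.38, at 35.1 ± 8.23 CPM in PD-1- cells), and Cd8a was not called (0.62 ± 0.70, edgeR adjusted p = 0.508). Gata1, the single erythroid marker tested, was lower (-3.63 ± 0.59), as was Pecam1, the single endothelial marker (-1.38 ± 0.14), and 0 neutrophil markers could be tested. Gating on CD45 and TCRb removes whole hepatocytes and B cells but not RNA freed from them.

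At 5 days, PD-1+ cells already had more transcripts of the Th1 gene Tbx21 and the glycolysis gene Ldha than PD-1- cells (n = 2 libraries per group). Tbx21 was at 2.84 ± 0.805 CPM in PD-1- and 188 ± 11.8 CPM in PD-1+ cells (6.10 ± 0.38, edgeR adjusted p = 9.25e-08), and Pdcd1 differed by 7.84 ± 0.32 (edgeR adjusted p = 1.31e-10). Ldha, which turns pyruvate to lactate, was at 1201 ± 9.46 and 5495 ± 588 CPM (2.19 ± 0.13, edgeR adjusted p = 3.58e-09). Satb1, a chromatin organiser of thymocytes and naive T cells, was lower (-2.66 ± 0.17, edgeR adjusted p = 6.61e-09), and Izumo1r was not called (-0.17 ± 0.17, edgeR adjusted p = 0.459). With edgeR, 2021 genes were higher and 1915 lower at 5 days, 3936 in all and 2298 without PD-1+ 5-day replicate 2.

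At 10 days, PD-1+ cells also had more Izumo1r, and very little Satb1 and Il7r, beside PD-1- cells (n = 2 libraries per group). Izumo1r was at 75.6 ± 7.11 CPM in PD-1- and 443 ± 31.5 CPM in PD-1+ cells (2.56 ± 0.17, edgeR adjusted p = 9.02e-09). Satb1 was at 1675 ± 39.0 and 29.0 ± 8.73 CPM (-5.85 ± 0.20, edgeR adjusted p = 9.66e-12), Il7r, the receptor chain for the survival cytokine IL-7, was lower (-4.92 ± 0.23) and Tox, a nuclear factor of chronically stimulated T cells, was higher (2.14 ± 0.18) (edgeR adjusted p = 2.60e-10 and 1.26e-07). Pdcd1 differed by 8.57 ± 0.31 and Lag3 by 7.70 ± 0.41 (edgeR adjusted p = 2.07e-11 and 8.50e-07). With edgeR, 1881 genes were higher and 1483 lower, 3364 in all and 2203 without PD-1- 10-day replicate 1. Of the genes called at the separate ages, 1206 were higher and 1007 lower at both, where independent lists would share 331 and 247, and 18 were called in opposite directions. Both ages were tested in 1 fit with 1 estimate of spread per gene, so some excess over 331 and 247 was built in.

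Between 5 and 10 days, Ppp1r15a and Dusp1 rose and Cox5a and Il2ra fell over both populations together (n = 4 libraries per age). The PD-1- and PD-1+ libraries of an age may share animals or pools, so these 4 may not be independent. Ppp1r15a, which restarts translation after stress, rose by 1.27 ± 0.13 and Dusp1, which switches off MAP kinases, by 1.29 ± 0.13 (edgeR adjusted p = 0.000181 for each). Cox5a, a subunit of cytochrome oxidase, changed by -1.01 ± 0.14 and Il2ra, the high-affinity IL-2 receptor chain, by -2.14 ± 0.35 (edgeR adjusted p = 0.00201 and 0.00621). The call of Il2ra was lost without PD-1+ 5-day replicate 2 (edgeR adjusted p = 0.0556). Armc7 (1.52 ± 0.23), an armadillo-repeat gene, rose and Dnajc15 (-1.15 ± 0.20), a mitochondrial chaperone, fell (edgeR adjusted p = 0.00534 and 0.00720), but neither was called with a term for sex or without the male pair. With edgeR, 264 genes rose and 296 fell, 560 in all, or 57 with a term for sex, and the count without 1 library was 56 (PD-1+ 5-day replicate 2), 77 (PD-1+ 5-day replicate 3), 334 (PD-1- 10-day replicate 1), 187 (PD-1+ 10-day replicate 1) or 110 (PD-1+ 10-day replicate 2).

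Of co-inhibitory genes over both populations, 5 of 12 had risen, 0 fallen and 7 not called. Co-inhibitory genes adjusted over the list alone gave 8 risen and 0 fallen (camera adjusted p = 5.49e-07, adjusted p = 0.250 with an estimated correlation). Of anergy genes, 3 of 15 had risen, 0 fallen and 12 not called. Anergy genes adjusted over the list alone gave 5 risen and 0 fallen (camera adjusted p = 0.000136, adjusted p = 0.282 with an estimated correlation). Of stress and dissociation genes, 6 of 16 had risen, 0 fallen and 10 not called. Stress genes adjusted over the list alone gave 8 risen and 1 fallen (camera adjusted p = 9.71e-05, adjusted p = 0.250 with an estimated correlation). Of follicular helper genes, 3 of 13 had risen, 0 fallen and 10 not called. Follicular helper genes adjusted over the list alone gave 4 risen and 0 fallen (camera adjusted p = 0.00593, adjusted p = 0.453 with an estimated correlation). Of mitosis genes, 0 of 23 had risen, 9 fallen and 14 not called. Mitosis genes adjusted over the list alone gave 0 risen and 22 fallen (camera adjusted p = 2.00e-17, adjusted p = 0.355 with an estimated correlation). Aurkb changed by -0.87 ± 0.17, a call lost without PD-1+ 5-day replicates 2 or 3 or PD-1+ 10-day replicate 2, and with a term for sex or without the male pair (edgeR adjusted p = 0.0575 to 0.145). Of oxidative phosphorylation genes, 0 of 24 had risen, 10 fallen and 14 not called. Respiratory genes adjusted over the list alone gave 0 risen and 19 fallen (camera adjusted p = 1.78e-14, adjusted p = 0.250 with an estimated correlation). Of glycolysis genes, 0 of 16 had risen, 5 fallen and 11 not called. Glycolysis genes adjusted over the list alone gave 0 risen and 11 fallen (camera adjusted p = 9.06e-08, adjusted p = 0.448 with an estimated correlation). Of DNA replication genes, 0 of 23 had risen, 3 fallen and 20 not called. DNA replication genes adjusted over the list alone gave 0 risen and 10 fallen (camera adjusted p = 4.80e-07, adjusted p = 0.272 with an estimated correlation). 

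Of NK cell genes over both populations, 0 of 7 had risen, 0 fallen and 7 not called. NK genes adjusted over the list alone gave 3 risen and 0 fallen (camera adjusted p = 0.0105, adjusted p = 0.453 with an estimated correlation). Of Th1 and cytotoxic genes, 3 of 18 had risen, 1 fallen and 14 not called. Th1 and cytotoxic genes adjusted over the list alone gave 4 risen and 1 fallen (camera adjusted p = 0.0105, adjusted p = 0.453 with an estimated correlation). NK cells lack TCRb and should have been removed by the sort, and innate-like T cells that carry CD4 and TCRb would have passed it. Of naive genes, 0 of 19 had risen, 1 fallen and 18 not called. Naive genes adjusted over the list alone gave 0 risen and 4 fallen (camera adjusted p = 0.0243, adjusted p = 0.453 with an estimated correlation). Of interferon response genes, 0 of 27 had risen, 2 fallen and 25 not called. Interferon response genes adjusted over the list alone gave 0 risen and 2 fallen (camera adjusted p = 0.0109, adjusted p = 0.638 with an estimated correlation). Camera called 12 lists, 6 in each direction, against 0 with an estimated correlation, where 4 lists had an unadjusted p below 0.05, and 5 by fry.

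Few genes were called between 5 and 10 days in PD-1- cells, and those that fell included interferon-inducible genes (n = 2 libraries per group). Ppp1r15a rose by 1.35 ± 0.15, Dusp1 by 1.19 ± 0.15 and Junb, an AP-1 subunit, by 0.93 ± 0.12 (edgeR adjusted p = 0.000966, 0.00289 and 0.00289). These 3 calls held without any 1 library. Rtp4, an interferon-inducible chaperone of receptors, fell from 131 ± 70.6 to 24.7 ± 0.844 CPM (-2.41 ± 0.35, edgeR adjusted p = 0.00979), and Gbp5, a guanylate-binding protein of inflammasome assembly, from 21.3 ± 8.41 to 2.43 ± 1.60 CPM (-2.97 ± 0.53, edgeR adjusted p = 0.0265). The immunity GTPase Irgm2 changed by -1.89 ± 0.28 on the log2 scale, and Irf1, an activator of interferon-stimulated genes, by -0.96 ± 0.17 (edgeR adjusted p = 0.00979 and 0.0214). All 4 were lost without PD-1- 5-day replicate 2, PD-1- 10-day replicate 1 or PD-1- 10-day replicate 2, Gbp5 and Irf1 also without either PD-1+ 5-day library, and Rtp4 and Gbp5 also with limma-voom (adjusted p = 0.0585 to 0.326).

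With edgeR, 17 genes rose and 14 fell in PD-1- cells, 31 in all, with 1219 at unadjusted p below 0.05. Which direction held more genes depended on the setting. With a term for sex 22 rose and 50 fell, without a count filter 64 and 116, and with DESeq2 28 and 44. Under RLE scaling 18 rose and 13 fell, and with limma-voom 15 and 13. Without 1 library the count was 16 (PD-1- 5-day replicate 2), 83 (PD-1- 5-day replicate 3), 17 (PD-1+ 5-day replicate 2), 17 (PD-1+ 5-day replicate 3), 7 (PD-1- 10-day replicate 1), 5 (PD-1- 10-day replicate 2), 47 (PD-1+ 10-day replicate 1) or 47 (PD-1+ 10-day replicate 2). Of interferon response genes, 0 of 27 had risen, 2 fallen and 25 not called. Interferon response genes adjusted over the list alone gave 0 risen and 9 fallen (camera adjusted p = 1.05e-14, adjusted p = 0.305 with an estimated correlation). Of oxidative phosphorylation genes, 0 of 24 had risen, 1 fallen and 23 not called. Respiratory genes adjusted over the list alone gave 0 risen and 13 fallen (camera adjusted p = 3.31e-08, adjusted p = 0.305 with an estimated correlation). Of mitosis genes, 0 of 23 had risen, 0 fallen and 23 not called. Mitosis genes adjusted over the list alone gave 0 risen and 0 fallen (camera adjusted p = 1.05e-07, adjusted p = 0.415 with an estimated correlation). Of stress and dissociation genes, 2 of 16 had risen, 0 fallen and 14 not called. Stress genes adjusted over the list alone gave 6 risen and 0 fallen (camera adjusted p = 5.38e-05, adjusted p = 0.305 with an estimated correlation). Of Th1 and cytotoxic genes, 1 of 18 had risen, 0 fallen and 17 not called. Th1 and cytotoxic genes adjusted over the list alone gave 3 risen and 0 fallen (camera adjusted p = 5.38e-05, adjusted p = 0.305 with an estimated correlation).

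Lists of other cells also moved with age in PD-1- cells. Of NK cell genes, 0 of 7 had risen, 0 fallen and 7 not called. NK genes adjusted over the list alone gave 2 risen and 0 fallen (camera adjusted p = 0.000117, adjusted p = 0.305 with an estimated correlation). Of innate-like and NKT genes, 0 of 12 had risen, 0 fallen and 12 not called. Innate-like genes adjusted over the list alone gave 3 risen and 0 fallen (camera adjusted p = 0.00174, adjusted p = 0.305 with an estimated correlation). Of gamma-delta T cell genes, 0 of 5 had risen, 0 fallen and 5 not called. Gamma-delta genes adjusted over the list alone gave 1 risen and 0 fallen (camera adjusted p = 0.0433, adjusted p = 0.305 with an estimated correlation). NK and gamma-delta T cells lack TCRb and should have been removed by the sort, so whether innate-like T cells or carried-over cells added to the Th1 list was left untested. Of macrophage and Kupffer genes, 0 of 6 had risen, 0 fallen and 6 not called. Macrophage genes adjusted over the list alone gave 1 risen and 4 fallen (camera adjusted p = 0.000365, adjusted p = 0.305 with an estimated correlation). Of B cell genes, 0 of 7 had risen, 0 fallen and 7 not called. B cell genes adjusted over the list alone gave 0 risen and 3 fallen (camera adjusted p = 0.00452, adjusted p = 0.305 with an estimated correlation).

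More genes were called with age in PD-1+ than in PD-1- cells, with Lag3, Tox and Izumo1r rising and Satb1 and Ldha falling (n = 2 libraries per group). Lag3 rose from 91.3 ± 13.6 to 1085 ± 502 CPM (3.57 ± 0.30, edgeR adjusted p = 0.000120) and Tox from 60.7 ± 10.9 to 361 ± 19.6 CPM (2.57 ± 0.18, edgeR adjusted p = 2.34e-07). Izumo1r rose from 90.7 ± 7.44 to 443 ± 31.5 CPM (2.29 ± 0.17, edgeR adjusted p = 2.48e-07). H2-Q7, a nonclassical class I gene, rose from 23.1 ± 0.875 to 473 ± 106 CPM (4.36 ± 0.22, edgeR adjusted p = 4.69e-09) and its close paralog H2-Q6 by 4.94 ± 0.28 (edgeR adjusted p = 6.29e-08), although short reads are not always separable between them. Satb1 fell from 235 ± 23.2 to 29.0 ± 8.73 CPM (-3.02 ± 0.18, edgeR adjusted p = 5.23e-08) and Ldha from 5495 ± 588 to 1769 ± 169 CPM (-1.63 ± 0.13, edgeR adjusted p = 6.34e-07). Pdcd1 rose by 1.03 ± 0.18 (edgeR adjusted p = 0.00133).

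With edgeR, 849 genes rose and 802 fell in PD-1+ cells, 543 and 332 of them by 2-fold or more, 1651 in all. The count was 481 without PD-1+ 5-day replicate 2, 797 without PD-1+ 5-day replicate 3, 727 without PD-1+ 10-day replicate 1 and 1082 without PD-1+ 10-day replicate 2. Other large rises were those of Gimap7, a GTPase of lymphocyte survival (2.88 ± 0.31), Rgs16, which shortens G-protein signalling (2.55 ± 0.22), and the macrophage growth factor Csf1 (3.96 ± 0.56). Ggt1, which breaks down extracellular glutathione (-3.54 ± 0.35), Furin, a proprotein convertase (-2.94 ± 0.25), and Gpr18, a lipid receptor (-2.50 ± 0.29), fell. Among these 6 genes the edgeR adjusted p was 1.90e-06 to 0.000409. Ccl5, a chemokine for T cells and monocytes, went from 23.8 ± 0.138 to 3566 ± 2286 CPM (7.23 ± 1.30, edgeR adjusted p = 0.0376), a call lost without any 1 of the 6 libraries other than the 5-day PD-1- ones, with 1 added term for sex, with a random replicate block, without the count filter or without the male pair (adjusted p = 0.0551 to 0.224). Ifng was not called (-0.46 ± 0.49, edgeR adjusted p = 0.610).

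Of co-inhibitory genes in PD-1+ cells, 5 of 12 had risen, 0 fallen and 7 not called. Co-inhibitory genes adjusted over the list alone gave 8 risen and 0 fallen (camera adjusted p = 7.76e-10, adjusted p = 0.0795 with an estimated correlation). Tigit rose by 2.29 ± 0.23. Of anergy genes, 8 of 15 had risen, 0 fallen and 7 not called. Anergy genes adjusted over the list alone gave 9 risen and 1 fallen (camera adjusted p = 1.17e-06, adjusted p = 0.151 with an estimated correlation). Nt5e rose by 2.25 ± 0.27 and Nrp1 by 1.18 ± 0.17. Of follicular helper genes, 6 of 13 had risen, 0 fallen and 7 not called. Follicular helper genes adjusted over the list alone gave 8 risen and 0 fallen (camera adjusted p = 4.54e-06, adjusted p = 0.156 with an estimated correlation). Maf rose by 1.86 ± 0.27. Of naive T cell genes, 1 of 19 had risen, 5 fallen and 13 not called. Naive genes adjusted over the list alone gave 1 risen and 7 fallen (camera adjusted p = 7.95e-06, adjusted p = 0.311 with an estimated correlation). Of glycolysis genes, 0 of 16 had risen, 15 fallen and 1 not called. Glycolysis genes adjusted over the list alone gave 0 risen and 15 fallen (camera adjusted p = 2.31e-21, adjusted p = 0.154 with an estimated correlation). The enzymes Tpi1 (-1.95 ± 0.16), Aldoa (-1.70 ± 0.16) and Pgk1 (-1.65 ± 0.18) fell with Ldha. Of oxidative phosphorylation genes, 0 of 24 had risen, 15 fallen and 9 not called. Respiratory genes adjusted over the list alone gave 0 risen and 21 fallen (camera adjusted p = 1.80e-10, adjusted p = 0.166 with an estimated correlation). Cox5a changed by -1.04 ± 0.17. Of mitosis genes, 0 of 23 had risen, 11 fallen and 12 not called. Mitosis genes adjusted over the list alone gave 0 risen and 16 fallen (camera adjusted p = 5.16e-11, adjusted p = 0.483 with an estimated correlation). Of DNA replication genes, 0 of 23 had risen, 12 fallen and 11 not called. DNA replication genes adjusted over the list alone gave 0 risen and 13 fallen (camera adjusted p = 3.27e-06, adjusted p = 0.189 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, changed by -1.10 ± 0.19.

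Of stress and dissociation genes in PD-1+ cells, 7 of 16 had risen, 2 fallen and 7 not called. Stress genes adjusted over the list alone gave 8 risen and 2 fallen (camera adjusted p = 0.0207, adjusted p = 0.433 with an estimated correlation). T cell receptor activation genes split by direction: 5 of 22 had risen, 5 fallen and 12 not called. Receptor activation genes adjusted over the list alone gave 5 risen and 5 fallen (camera adjusted p = 0.905). Egr1, an immediate early factor, rose by 1.61 ± 0.23. Of Th1 and cytotoxic genes, 5 of 18 had risen, 2 fallen and 11 not called. Th1 and cytotoxic genes adjusted over the list alone gave 6 risen and 3 fallen (camera adjusted p = 0.519). The IL-18 receptor chain Il18r1 fell (-1.37 ± 0.23). Of Th2 genes, 1 of 9 had risen, 1 fallen and 7 not called. Th2 genes adjusted over the list alone gave 2 risen and 2 fallen (camera adjusted p = 0.969). Areg rose from 10.0 ± 3.33 to 70.3 ± 16.8 CPM (2.81 ± 0.39), Ccr4 fell (-2.44 ± 0.35) and Gata3 was not called (-0.20 ± 0.18, edgeR adjusted p = 0.508). Of homing and residency genes, 5 of 23 had risen, 6 fallen and 12 not called. Homing genes adjusted over the list alone gave 5 risen and 6 fallen (camera adjusted p = 0.642). Itga4, an integrin chain that binds VCAM-1, rose by 1.52 ± 0.16. Of interferon response genes, 4 of 27 had risen, 1 fallen and 22 not called. Interferon response genes adjusted over the list alone gave 4 risen and 1 fallen (camera adjusted p = 0.459). The DNA-binding Ifi209 rose by 1.59 ± 0.21.

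The PD-1 difference of Izumo1r, Satb1 and Ldha changed with age (n = 2 libraries per group). Izumo1r differed between PD-1+ and PD-1- cells by -0.17 at 5 days and 2.56 at 10 days, an interaction of 2.72 ± 0.23 (edgeR adjusted p = 7.63e-06). Satb1 went from -2.66 to -5.85, an interaction of -3.19 ± 0.24 (edgeR adjusted p = 2.80e-06), and Ldha from 2.19 to 0.89, an interaction of -1.30 ± 0.18 (edgeR adjusted p = 0.000880). H2-Q7 (3.73 ± 0.29), Syt11, a regulator of vesicle traffic (3.53 ± 0.46), Cst7, a protease inhibitor of granules (2.82 ± 0.40), and Tox (1.96 ± 0.26) had positive interactions. Gpr183, an oxysterol receptor that guides cells to B cell areas (-2.68 ± 0.32), had a negative one. Among these 5 genes the edgeR adjusted p was 3.22e-06 to 0.00118.

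With edgeR, 244 genes had an interaction, 138 positive and 106 negative, or 483 with the replicate number as a block and 469 without a count filter. In simulated data the interaction test found only 7% of 2-fold and 40% of 4-fold changes, so the true number stays unknown. The count was 124 without PD-1- 5-day replicate 2, 57 without PD-1+ 5-day replicate 2, 104 without PD-1+ 5-day replicate 3, 86 without PD-1- 10-day replicate 1, 100 without PD-1- 10-day replicate 2 and 91 without PD-1+ 10-day replicate 1. Of glycolysis genes, 0 of 16 were positive, 8 negative and 8 not called. Glycolysis genes adjusted over the list alone gave 0 positive and 14 negative (camera adjusted p = 2.21e-17, adjusted p = 0.355 with an estimated correlation). Of interferon response genes, 3 of 27 were positive, 0 negative and 24 not called. Interferon response genes adjusted over the list alone gave 11 positive and 0 negative (camera adjusted p = 4.63e-09, adjusted p = 0.432 with an estimated correlation). Of naive T cell genes, 0 of 19 were positive, 3 negative and 16 not called. Naive genes adjusted over the list alone gave 2 positive and 6 negative (camera adjusted p = 1.08e-05, adjusted p = 0.355 with an estimated correlation). Genes called for age in both populations shared a direction in 15 cases and were opposite in 1.

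**Figure D4:**
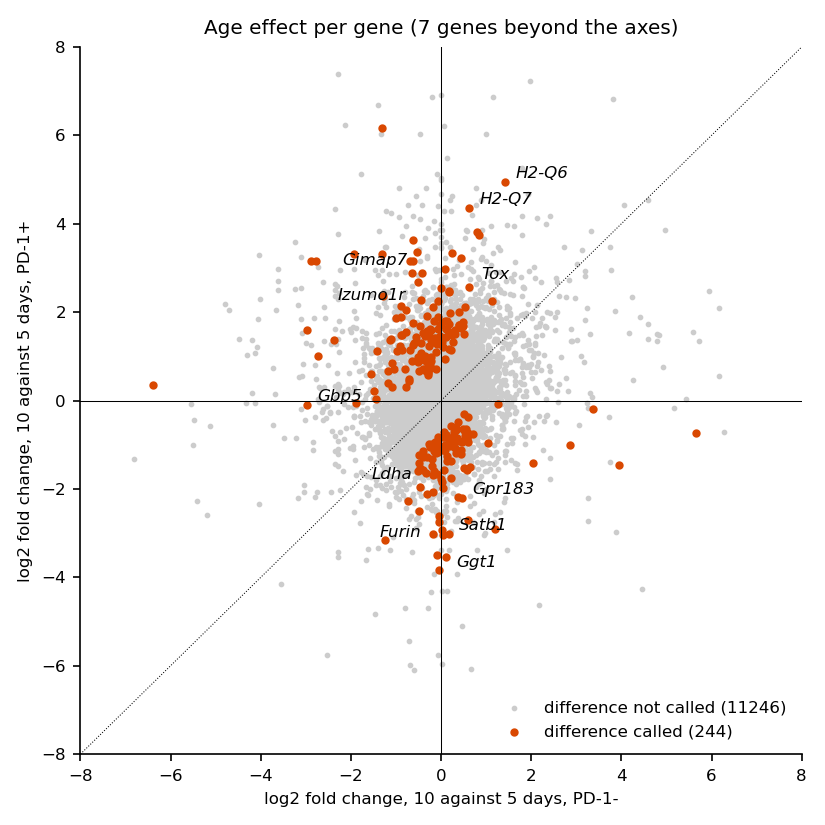
Age effect of each tested gene in PD-1- cells against PD-1+ cells. Coloured genes had a called interaction.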

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

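The tests of the patterns below were chosen after the results had been seen.

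The PD-1 difference depended on age for 244 genes. The interactions listed next, on the log2 scale, are only those of genes given in this text, and other genes had called interactions as large. Positive ones were H2-Q7 3.73, Syt11 3.53, H2-Q6 3.52, Gimap7 3.30, Gbp5 2.87, Cst7 2.82, Izumo1r 2.72 and Rgs16 2.56. Smaller positive ones were Cd8b1 2.15, Tox 1.96, Irgm2 1.83, Ifi209 1.82, Itga4 1.25, H2-K1 1.18 and Nr4a2 1.13. Negative ones were Ldha -1.30, Il7r -1.34, Tpi1 -1.47, Aldoa -1.51, Pgk1 -1.56, Gpr18 -1.999, Gpr183 -2.68, Furin -2.95, Satb1 -3.19 and Ggt1 -3.64. Without PD-1+ 5-day replicate 2 the interactions of Cd8b1, Gbp5, Il7r, Irgm2, Itga4, Nr4a2, Pgk1 and Rgs16 were no longer called, and without PD-1+ 5-day replicate 3 or PD-1- 10-day replicate 1 that of Gpr18 was not. All but Itga4, Pgk1 and Gpr18 were also lost without other libraries (edgeR adjusted p = 0.0508 to 0.346), and calls were lost without the male pair (Cd8b1, Gbp5, Gpr18, Il7r, Irgm2 and Nr4a2), with a term for sex (Cd8b1), after thinning (Cd8b1, Il7r, Nr4a2 and Rgs16), with DESeq2 (Cd8b1 and Nr4a2) or with limma-voom (Cd8b1, Gbp5, Il7r, Nr4a2 and Rgs16), at adjusted p = 0.0531 to 0.431 over edgeR and these methods. By camera the interaction also had an adjusted p of 2.21e-17 for glycolysis, 4.63e-09 for interferon response, 1.08e-05 for naive quiescence, 0.00373 for each of mitosis, follicular helper and macrophage genes, 0.0107 for anergy, 0.0160 for oxidative phosphorylation, 0.0242 for DNA replication and 0.0319 for each of co-inhibitory receptors and gamma-delta T cell genes. With an estimated correlation the adjusted p was 0.355 or more for each of these lists.

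H2-Q6 and H2-Q7, near-identical class I genes, were higher in 10-day PD-1+ cells. A mere shift of reads between paralogs would leave the sum of the 8 H2-Q genes level, but that sum rose by 3.41 on the log2 scale, from 101 and 109 to 1241 and 986 CPM. A difference of H2-Q haplotype between the 5-day and 10-day mice that acted alike in both populations would give no interaction. The smaller of the 2 interactions was 3.52 ± 0.43. In PD-1- cells mean H2-Q6 went from 10.1 to 28.1 CPM and H2-Q7 from 36.9 to 57.8 CPM. A haplotype difference that acted mainly in PD-1+ cells could not be told apart. Of 11 other class I pathway genes, 7 rose with age in PD-1+ cells and 0 fell, H2-K1 among those that rose (1.22 ± 0.13, edgeR adjusted p = 1.45e-05, chosen after its values were seen) and 3 only narrowly (edgeR adjusted p = 0.0442 to 0.0472), but 24 of 38 proteasome genes fell and 0 rose, so whether class I presentation as a whole rose stays open. Clones or litters that differ between the ages stay as an open, untested cause.

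Far more genes were called with age in PD-1+ than in PD-1- cells, 1651 against 31. At unadjusted p below 0.05 (edgeR) the counts were 3249 and 1219, and the direct test of the interaction called 244 genes. The adjusted cut-off loosens as more genes change, so ratios of called genes overstate the difference, and few calls in PD-1- cells do not mean little change. Lower depth of the PD-1- libraries would remove the excess at equal totals, yet the ratio of calls was 44.4 after thinning (1287 against 29). Without the male pair it was 13.1 (943 against 72), which leaves 1 library in each 5-day group, assumed to vary like the other groups. The variance of age log2 fold changes, less that of replicates, was 7.02 times larger in PD-1+ cells, so wider spread between PD-1- replicates does not account for it. A change in which clones or subsets make up the PD-1+ gate, rather than a change within cells, stays open and untested.

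Interferon response genes were lower at 10 days in PD-1- cells, though few passed singly. Both 10-day libraries were below both 5-day libraries for 17 of 27 members, but the median log2 ratio to the 10-day mean was 1.46 ± 0.84 in the higher 5-day library and 0.48 ± 0.79 in the lower (standard deviation over members), so 1 high 5-day library cannot be told apart from a change with age. Macrophage and B cell lists fell too (camera adjusted p = 0.000365 and 0.00452), but RNA lost with antigen-presenting, B or Kupffer cells could account for little of the fall, since 5 abundant transcripts of such cells fell by 0.640% of the fall of the interferon members, 20.6 against 3219 CPM, which does not bound the signals those cells gave. Against a settled change, camera lost the calls of all 3 lists (adjusted p = 0.305 with an estimated correlation for each). Whether an interferon exposure of the 5-day litters or a developmental change lies behind it stays open and untested.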

How the results depend on the processing

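The alternatives were planned before the data were seen except the term for sex, the removal of the male pair and the removal of gene models overlapping ribosomal RNA. Counts stayed within 1.5 times the main count in all but the following. Against a fold of 1.5, glmTreat called 2220 genes for PD-1 over both ages, 2008 at 5 days and 1774 at 10 days, 23 for age over both populations, 0 in PD-1- cells (377 at unadjusted p below 0.05, and 72 by DESeq2 and 28 by limma-voom against no change), 357 in PD-1+ cells and 51 for the interaction. Without a count filter, 984 genes were called for age over both populations, 180 for age in PD-1- cells and 469 for the interaction. DESeq2 called 72 for age in PD-1- cells and limma-voom 962 for age over both populations. A term for sex gave 57 for age over both populations and 72 for age in PD-1- cells. Without the male pair, 2426 genes were called for PD-1 at 5 days, 56 for age over both populations, 72 for age in PD-1- cells, 943 for age in PD-1+ cells and 118 for the interaction. For the gene lists, 9 were called for PD-1 and 0 for age with an estimated correlation, and fry called 5 for age. Leaving out 1 library gave 3971 to 4374 genes for PD-1 over both ages, 2298 to 3936 at 5 days, 2203 to 3485 at 10 days, 56 to 754 for age over both populations, 5 to 83 in PD-1- cells, 481 to 1804 in PD-1+ cells, 57 to 261 for the interaction, 14 to 18 lists for PD-1 and 9 to 14 lists for age. Where 1 library was left in a group, as in these fits and without the male pair, it was assumed to vary like the other groups.

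Library numbers are shared between the PD-1- and PD-1+ libraries of an age, but correlations of the residuals of same-numbered libraries were 0.0938 at 5 days (0.04998 without sex-linked genes) and 0.114 at 10 days, over too few pairs to settle it. Both 5-day libraries numbered 3 were male and both numbered 2 female, as shared mice or pools would give, so sharing stays open, and with it the age comparison would rest on 2 animals or pools per age. With the number as a fixed block, 4399, 4158 and 3563 genes were called for PD-1 over both ages, at 5 and at 10 days, 483 for the interaction, and 17 lists for PD-1. As a random block in limma-voom it gave 1235 genes for age over both populations, 30 in PD-1- cells and 1803 in PD-1+ cells, with consensus correlations of -0.149 and 0.0806.

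Of the 3165 results for named genes under other settings, covering 151 pairs of gene and comparison, 0 reversed direction. Leaving out 1 library left 1137 the same, 2 stronger and 69 weaker or no longer called. The other settings left 1898 the same, 1 stronger and 58 weaker or no longer called, most often under glmTreat and without the male pair.

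Of the splits of the 8 libraries 4 against 4, 18 keep the other factor balanced. The true grouping gave 4761 genes for PD-1 and 560 for age, which 1 of the 18 splits reached for each, itself, and the highest count of any other was 0 and 15. With 18 splits a share under 0.05 cannot be had. In every other split the true PD-1 or age difference was left out of the model and widened the spread. In the PD-1 run even the split by age gave 0 genes. The low counts of the other splits were thus largely built in, and they do not weigh against chance.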

Other observations

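The gene families and receptor segments here were chosen after the results had been seen.

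Most proteasome genes were higher and most ribosomal protein genes lower in PD-1+ cells. Of 38 proteasome subunit genes, which degrade tagged proteins and make peptides for class I, 35 were higher and 0 lower in PD-1+ cells over both ages, and 0 rose and 24 fell between 5 and 10 days in PD-1+ cells. Of 78 ribosomal protein genes, 2 were higher and 51 lower in PD-1+ cells, and 0 rose and 49 fell with age in PD-1+ cells. Of 76 mitochondrial ribosome genes, 31 were higher and 2 lower in PD-1+ cells. The directions held under RLE and upper-quartile scaling, with 35 and 31 proteasome genes higher in PD-1+ cells. Families move together, and with an estimated correlation camera called none of proteasome (adjusted p = 0.305 for PD-1 and 0.0930 for age), ribosomal protein (adjusted p = 0.600 and 0.144) and mitochondrial ribosome genes (adjusted p = 0.305 for PD-1). Ribosomal protein genes have many pseudogenes that share their short reads.

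Of 13 genes of the NF-kB pathway, which carries signals from antigen and TNF-family receptors, 10 were higher and 0 lower in PD-1+ cells (camera adjusted p = 3.36e-07, adjusted p = 0.0148 with an estimated correlation). Of 9 Gimap genes, GTPases that sustain lymphocyte survival, 7 rose and 0 fell with age in PD-1+ cells and 4 had a positive interaction, calls that camera lost with an estimated correlation (adjusted p = 0.0801 and 0.127). Of 3 Ifitm genes, interferon-inducible membrane proteins, 0 rose and 3 fell with age in PD-1+ cells (median log2 fold change -5.77, camera adjusted p = 1.95e-11, adjusted p = 0.0801 with an estimated correlation).

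Receptor variable segments were less diverse in PD-1+ libraries. With every library thinned to 153 counts, the effective number of Trav segments was 18.97 ± 4.94 in PD-1+ and 33.6 ± 4.83 in PD-1- libraries, and with 759 counts that of Trbv segments was 11.4 ± 2.13 and 14.5 ± 1.02 (mean ± standard deviation, n = 4 each). The exact permutation p was 0.0286 for each, adjusted p = 0.0286, the smallest that 4 against 4 libraries can give. It takes libraries of both ages as exchangeable and libraries that share a number as independent. Permuting within an age or within shared numbers leaves too few arrangements for a p below 0.05, so a stricter test could not have passed. A narrower, selected or clonally expanded PD-1+ population could give this. Thinning equalised counts but not the numbers of sorted cells or starting molecules, so a smaller PD-1+ input could not be told apart. Trbv15 held 37.0% of Trbv counts in 10-day PD-1+ replicate 1. The most used Trbv segment differed between the 2 libraries of 10-day PD-1+ cells, while Trbv3 led in both of 5-day PD-1+ cells (21.9% and 20.0%) and Trav4-4-dv10 led Trav counts in both of 10-day PD-1+ cells (17.0% and 12.1%) but also in 5-day PD-1- replicate 2 (8.88%), so whether they met a common antigen stays open and untested. Segment counts from 3'-primed short reads do not give clonotypes, so whether single clones had expanded stays open and untested.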
